A study of Arabidopsis thaliana with 3 samples.

How the data were processed

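Transcript levels in Arabidopsis rosettes were measured on 3 two-colour oligonucleotide arrays. Each array carried labelled RNA of the lsm1a lsm1b double mutant together with labelled RNA of Col-0, the wild type, so every value is a ratio within an array. Per the labels, the mutant RNA was in the Cy3 channel on arrays 1 and 3 and in the Cy5 channel on array 2, and the 3 arrays are biological replicates. Total RNA was extracted with Trizol, column purified, and amplified RNA was labelled with amine-reactive dyes, per the labels' protocols. The labels disagree about the plants. The sample characteristics give rosettes of 2-week-old plants and the growth protocol a long day of 16 h light and 8 h dark at 22 °C. The sample descriptions give 3-week-old plants kept for 1 day at 4 °C. Both genotypes carry the same labels, so this does not affect which RNAs are compared, but the growth temperature behind the comparison is open.

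The values used are the normalized log2 ratios that the authors deposited, 1 per probe and array, given to 2 decimals. limma is named in the submitters' processing notes, without a version. The background correction, the normalization within arrays, the log base and the sign of the ratio are not given in the sources used here. The log base was taken as 2, the scale of limma's ratios, from the range of the values, which ran from -6.76 to 5.87. The medians of the 3 columns were 0, 0.01 and -0.01, so the ratios are centred. No intensities were used, so probes close to background could not be recognised, and the number of arrays limits the precision. How ratios of dim probes were affected depends on steps that are not given, and a probe that matches its target poorly in 1 genotype gives a ratio that is not a transcript ratio.

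The direction of the ratios was set by a rule fixed before the data were examined. The dye-swapped array correlated above 0 with both others (Pearson r = 0.416 and 0.411 over probes), so the ratios had already been turned one way, and they were read as lsm1a lsm1b over Col-0. This direction is likely, not certain. Its basis is that the labels put the mutant in the first channel of every sample, whatever its dye, and name Col-0 the control. The sample titles list Col-0 first. If the ratio runs the other way, every direction given here turns, and the sizes and p-values stay. The planned check with the disrupted genes was not made, because LSM1A and LSM1B are not analysed here.

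Of 43656 rows, 55 were manufacturer control features and were left out of all tests of genes. The platform annotation, which can be old, gave 1 gene symbol for 34342 of the 43601 other probes, several for 0 and none for 9259. Names were updated through the RefSeq gene table of assembly TAIR10.1: 32240 probes matched by accession and 2015 by symbol, 42 were left unnamed because both pointed to different genes, and 45 matched no gene. The remaining 34255 probes named 24648 genes, of which 7299 had 2 or more probes. Probes of a gene were averaged on each array. Where the probe means of a gene named in the text differ by more than 1, this is said beside its value, and the medians of lists include members whose probes differ as much. No build is named for the array, so no coordinates are given. The first digit of a locus code is its chromosome, and the gene order of TAIR10.1 was used only for which genes are neighbours.

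The mean ratio of each gene over the 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, intercept only), with Benjamini-Hochberg adjustment over the 24648 genes and a threshold of 0.05. A dye term was left to an alternative, because with 2 arrays of one orientation and 1 of the other it leaves 1 residual degree of freedom. Fold changes are 2 to the power of the mean log2 ratio. The 21 gene lists with measured members, all fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. The other tests of the lists were camera with an estimated correlation and fry, which tests a list against 0 and not against other genes. The genes named in the text follow a rule fixed at the same time: the 10 highest and the 10 lowest mean ratios among genes past the threshold with 1 sign on all 3 arrays, and, of each list, up to 4 members past the threshold or otherwise up to 2 given as values. Genes named outside the rule are said to be so.

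The fit was tested on simulated ratios of 24648 genes with 200 changed genes and the spread of this comparison. It found 43.3% of genes changed by 1 on the log2 scale, 91.0% of those changed by 2 and 93.9% of those changed by 3, and 4.4% of its calls were false. With 2 simulated arrays it found 1.49%, 62.7% and 86.4%. The simulated arrays had independent noise and no dye or replicate difference, so these shares need not hold for the real arrays. In simulated lists of 15 independent genes, camera found 50 of 50 lists shifted by 0.5 and called 6 of 50 unshifted lists at an unadjusted p under 0.05. The position test found 20 of 20 clustered sets and 1 of 20 scattered sets. Alternatives covered the dye term, the turning of array 2, robust moderation, a one-sample t-test, centring, scale and quantile normalization, array weights, single probes, thresholds and leaving out each array, and for the lists the set test and the gene correlation. The lists cover the other LSM ring genes, decapping and mRNA decay factors, cold response, abscisic acid, nuclear photosynthesis genes, flavonoids, salicylic acid defence, jasmonate, rapidly induced touch, wound and ethylene genes, heat shock, oxidative stress, the circadian clock, glucosinolates, auxin, iron, senescence, markers of flowers, roots, seeds and the stomatal lineage, and reference genes. They hold 273 genes, of which 254 were measured. Random draws, figures and position tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.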

Results

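Rosette RNA of the lsm1a lsm1b double mutant was compared with that of Col-0 on 3 two-colour arrays, 1 per biological replicate. LSM1A and LSM1B are the 2 Arabidopsis copies of LSM1, the subunit that defines the cytoplasmic LSM1-7 ring, which binds the 3' end of messenger RNAs and promotes their decapping and decay. The comparison asks which transcripts differ in level when this ring lacks its LSM1 subunit. Ratios of 24648 genes were analysed on all 3 arrays, with a median standard deviation (SD) between arrays of 0.185 on the log2 scale. Over genes, arrays 1 and 3, which share a dye orientation, correlated at r = 0.745, and array 2, with the dyes swapped, correlated with them at r = 0.427 and 0.452. All ratios are given as lsm1a lsm1b over Col-0, the likely direction.

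Among genes past the threshold, the 10 with the largest rises were genes named here only by locus code. AT3G48640 was 27.4-fold higher in the mutant (mean log2 ratio 4.78 ± 0.56, SD, n = 3 arrays; adjusted p = 0.0232), and its 2 probes gave 4.77 and 4.78. AT5G26270 was 20.9-fold higher (4.39 ± 0.30; adjusted p = 0.00944), AT1G20070 was 12.7-fold higher (3.67 ± 0.60) and AT2G28570 was 12.6-fold higher (3.66 ± 0.24). AT4G14390, AT1G13470, AT1G12080, AT5G60260, AT5G44570 and AT4G35720 rose between 7.62-fold and 9.90-fold. The 3 probes of AT1G12080 lay between 3.18 and 3.24, and this gene had the smallest SD of the group (0.10). ICS1, which encodes the main enzyme of stress-induced salicylic acid synthesis, rose 1.96-fold (0.97 ± 0.16; adjusted p = 0.0465).

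ECS1 was 62.3-fold lower in the mutant (-5.96 ± 0.46; adjusted p = 0.00944), with -6.32, -5.44 and -6.12 on the 3 arrays. AT5G52420 was 28.8-fold lower (-4.85 ± 1.00; adjusted p = 0.0378) and varied most, from -5.54 on array 2 to -3.70 on array 3. The neighbouring genes AT1G23950, AT1G23960 and AT1G23970 fell together, by 18.6-fold, 15.8-fold and 6.38-fold. AT3G01345 fell 18.3-fold, with its 2 probes at -4.56 and -3.83. AT3G16670, AT1G27385, AT5G55790 and AT1G80130 fell between 5.84-fold and 7.85-fold. CHS, the chalcone synthase that starts flavonoid synthesis, fell 2.62-fold (-1.39 ± 0.31; adjusted p = 0.0456). Each of these genes except AT3G01345 was measured by 1 probe. With 1 probe, a lower transcript level cannot be told from a poorer match of the probe in the mutant.

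**Figure D1:**
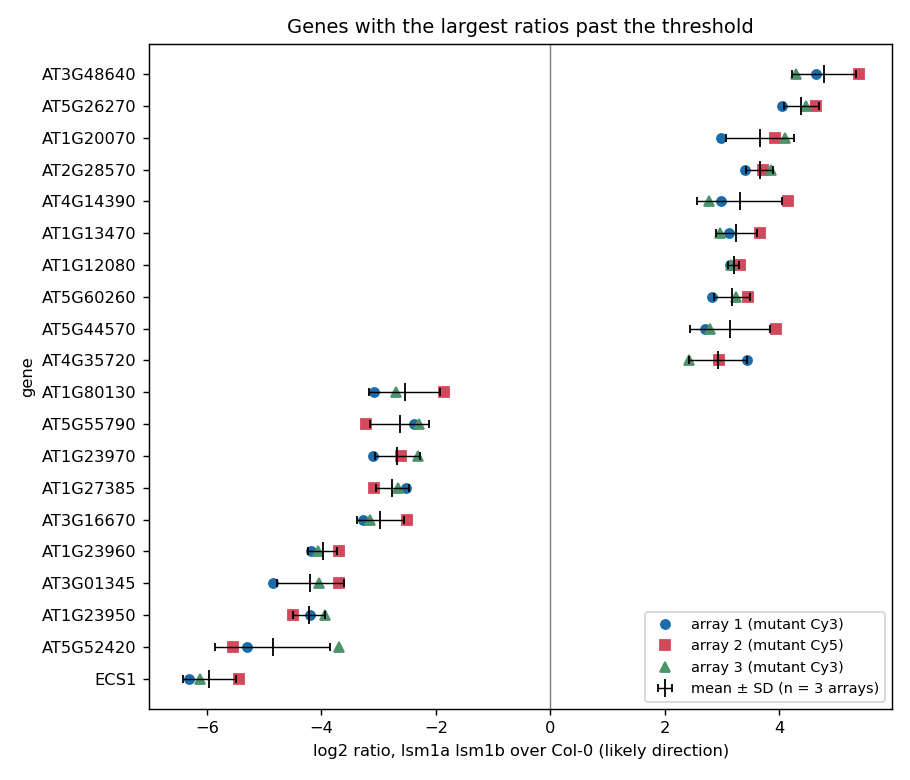
Log2 ratios (horizontal axis) of the 10 genes with the largest rises and the 10 with the largest falls past the threshold, with each array as a symbol and the mean ± SD over 3 arrays as a black bar. ECS1 lies between -6.32 and -5.44 on all arrays, and the highest gene, AT3G48640, between 4.30 and 5.39.

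In all, 298 genes passed the threshold, 154 higher and 144 lower in the mutant, and each of the 298 had the same sign on all 3 arrays. The change was at least 2-fold for 190 of them, 101 higher and 89 lower. The median change was 2.24-fold among the higher and 2.19-fold among the lower genes, and the smallest called change was 1.62-fold. These are adjusted p-values of limma's moderated test, the lowest of which was 0.00944, and 4944 genes had an unadjusted p under 0.05. The calls need all 3 arrays: without array 1, 2 or 3, and likewise with a dye term in the fit, 0 genes passed. In limma, 2804, 7326 and 2542 genes had an unadjusted p under 0.05 without array 1, 2 or 3, and 6389 with the dye term. All 298 kept their direction and an unadjusted p under 0.05 in each of these fits. They were chosen on the same arrays, and their shared sign fixed the direction.

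Salicylic acid defence genes were higher in the mutant as a list. Of 14 measured members, 13 were above 0 on all 3 arrays, 1 (ICS1) passed over all genes, and 12 passed when adjusted over the list alone. The list's median was 0.97, with 0.56, 1.503 and 0.90 on arrays 1, 2 and 3, and camera gave an adjusted p of 9.55e-08. This call is lost in camera with an estimated correlation (adjusted p = 0.578), a setting in which no list had an unadjusted p below 0.162. PR1, a classical salicylic acid marker, was chosen after its values were seen: it stood at 1.75, 5.71 and 2.11, a mean of 3.19 that did not pass (adjusted p = 0.146). PR2 and PR5 of the same list are likewise named outside the rule. PR2 stood at -0.04 ± 0.22, and PR5 at 0.96 ± 0.58 with probe means from -0.04 to 1.48.

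Heat shock and chaperone genes were also higher as a list (camera adjusted p = 0.0034; adjusted p = 0.578 with an estimated correlation). None of 14 members passed over all genes, while 7 higher and 1 lower passed when adjusted over the list alone. The cytosolic chaperone gene HSP70-4 stood at 1.37 ± 0.43 and the heat shock factor gene HSFA7A at 1.08 ± 0.58, neither past the threshold over all genes. The list medians were 0.26, 0.95 and 0.20 on arrays 1, 2 and 3, and the call is lost without array 2 (adjusted p = 0.162). Genes of abscisic acid synthesis and response were higher as a list (camera adjusted p = 0.00355; adjusted p = 0.578 with an estimated correlation), with a median of 0.27 and 0 of 19 members past the threshold over all genes. Its medians were 0.48, 0.06 and 0.34 on arrays 1, 2 and 3, so it lay near 0 on the dye-swapped array. Adjusted over the list alone, 2 were higher and 1 lower. NCED5, a gene of the rate-limiting step of abscisic acid synthesis, stood at 1.11 ± 0.81, and RAB18, a dehydrin gene, at 0.94 ± 0.66. The other NCED genes of the list, named outside the rule, were near 0, with NCED3 at 0.06 ± 0.10 and NCED9 at -0.02 ± 0.09.

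Nuclear photosynthesis genes were lower in the mutant as a list. All 17 measured members had a mean below 0, from -2.58 to -0.53, and 15 were below 0 on all 3 arrays. None passed over all genes, and 14 passed when adjusted over the list alone. The median was -1.05, with -0.89, -0.38 and -1.39 on arrays 1, 2 and 3 (camera adjusted p = 1.33e-09; adjusted p = 0.578 with an estimated correlation). LHCB1.1, which encodes a light-harvesting protein of photosystem II, stood at -1.55 ± 1.18. LHCB2.1 stood at -2.58 ± 1.21, but its 2 probes disagreed, with means of -4.81 and -0.35. The LHCB1 genes are near-identical copies whose probes can share signal.

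Flavonoid and anthocyanin genes were lower as a list (camera adjusted p = 7.05e-05; adjusted p = 0.578 with an estimated correlation). Of 16 members, 11 were below 0 on all 3 arrays, CHS alone passed over all genes, and 8 passed when adjusted over the list alone. The median was -0.50, with -0.32, -0.72 and -0.42 on arrays 1, 2 and 3.

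**Figure D2:**
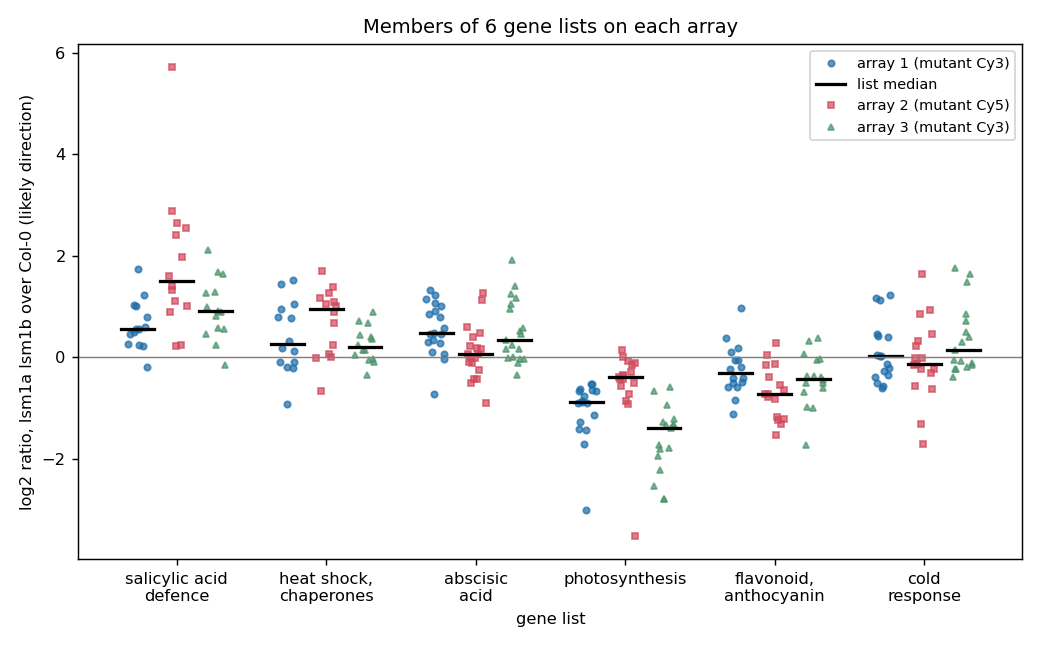
Log2 ratio (vertical axis) of every measured member of 6 gene lists on each array, with the list median per array as a black line. The photosynthesis medians lie at -0.89, -0.38 and -1.39 and the salicylic acid medians at 0.56, 1.503 and 0.90, whereas the cold-response medians lie at 0.02, -0.14 and 0.15.

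The cold-response list did not differ from other genes (camera adjusted p = 0.942). Its 17 measured members had a median of -0.05 and a mean of 0.15, 0 passed over all genes and 2 higher when adjusted over the list alone. The dehydrin genes ERD10 (1.25 ± 0.36; adjusted p = 0.0551) and COR47 (1.25 ± 0.47; adjusted p = 0.0715) had the largest ratios. Decapping and decay factors other than the LSM genes did not differ as a list (adjusted p = 0.143), with 0 of 18 past the threshold under either adjustment. SOV, a 3' to 5' exoribonuclease gene, stood at 0.75 ± 0.33 and XRN3, a nuclear exoribonuclease gene, at -0.32 ± 0.09. Of the other LSM ring genes, 2 of 9 were measured here. LSM4 stood at 0.65 ± 0.22 and LSM5 at 0.30 ± 0.25 (list adjusted p = 0.0756), with 0 past the threshold over all genes and 1 higher when adjusted over the list alone.

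Lists of jasmonate, rapidly induced, oxidative stress, clock, glucosinolate, auxin, iron and senescence genes did not pass camera, with adjusted p of 0.125, 0.117, 0.125, 0.93, 0.0756, 0.93, 0.961 and 0.098 in this order, and held 0 members past the threshold over all genes. Adjusted over the list alone, 1 jasmonate gene was higher and 3 lower, 4 oxidative stress genes were higher and 1 lower, 1 iron and 1 senescence gene were higher, and 0 passed in the others. The iron list had a median of -0.06 and a mean of 0.03. The largest absolute mean ratios were PDF1.2A, a defensin gene, at -2.70 ± 1.06, and VSP2 at -1.004 ± 0.52, with probe means from -1.76 to -0.25, among jasmonate genes, ERF11 at 1.28 ± 0.58 and WRKY40 at 1.14 ± 1.28 among rapidly induced genes, and SEN1 at 1.31 ± 0.95 and SAG13 at 1.17 ± 0.45 among senescence genes. MYB28, a regulator of aliphatic glucosinolates, stood at -1.24 ± 0.64 and MAM3 at -0.61 ± 0.29, and GSTU24 at 0.88 ± 0.65 and GSTF8 at 0.78 ± 0.18 among detoxification genes. NAS4 at 0.76 ± 0.18, PYE at 0.51 ± 0.26, IAA29 at -0.58 ± 0.19, IAA6 at -0.40 ± 0.46, ELF4 at 0.35 ± 0.24 and LHY at 0.34 ± 0.58 were the largest of the iron, auxin and clock lists. Lists of flower, root, seed and stomatal markers did not pass (adjusted p = 0.285, 0.942, 0.548 and 0.93), with 0 members past the threshold under either adjustment. The root list had a median of -0.01 and a mean of 0.01, and the stomatal list a median of 0.02 and a mean of -0.08. AP1 stood at 0.30 ± 0.27 and AP3 at 0.20 ± 0.23 for flowers, PHO1 at 0.15 ± 0.30 and SHR at -0.13 ± 0.13 for roots, CRU3 at -0.13 ± 0.15 and OLEO1 at -0.08 ± 0.11 for seeds, and FAMA at -0.37 ± 0.54 and MYB60 at 0.13 ± 0.31 for the stomatal lineage. The 8 reference genes did not pass as a list (adjusted p = 0.696) and had a median of 0.10, with GAPC1 at 0.20 ± 0.25 and SAND at 0.18 ± 0.34.

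Genes lower in the mutant lay closer together on the chromosomes than random gene sets, in tests chosen after the data were seen. In the gene order of TAIR10.1, the 144 lower genes formed 133 pairs that lay 10 to 100 measured genes apart, against a median of 75 and a central range of 59 to 93 in 10000 random gene sets (permutation p = 0.0001, one-sided, the smallest these draws can give). The 154 higher genes formed 85 such pairs, against a median of 86 (permutation p = 0.55). The pair counts of lower and higher genes were not compared with each other, and the shares of lower and higher genes by chromosome gave a permutation p of 0.054. Genes below -2 on both arrays 1 and 2 numbered 47 and formed 24 pairs, against a median of 8 and a central range of 3 to 14 (permutation p = 0.0001). Of the windows of 200 neighbouring genes, AT3G43291 to AT3G45490 held 6 such genes, AT1G23700 to AT1G26680 and AT2G03180 to AT2G05720 held 4 each, and AT3G45500 to AT3G47590 and AT5G44270 to AT5G46200 held 3 each. Array 3 had 4 genes below -2 in the window on chromosome 1, 3 in that on chromosome 5 and 0 in those on chromosomes 2 and 3. Genes below -2 on all 3 arrays numbered 3 in the window on chromosome 1 and 1 in that on chromosome 5. On the whole of chromosome 1 they numbered 5. ECS1 (AT1G31580) and AT1G27385 are among these 5 but lie in other windows of chromosome 1, each with 1 such gene. LSM1A (AT1G19120) lies on the same chromosome, and whether its position bears on these falls was not tested. AT1G23950, AT1G23960 and AT1G23970, named above, lie in the window from AT1G23700 on chromosome 1, and LHCB2.1 lies in that on chromosome 2. AT5G44570, among the 10 largest rises, and PDF1.2A lie in that on chromosome 5. Without the 5 windows, camera gave the jasmonate list an adjusted p of 0.455, against 0.125 with them. The 5 lists past the threshold stayed so without the windows.

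**Figure D3:**
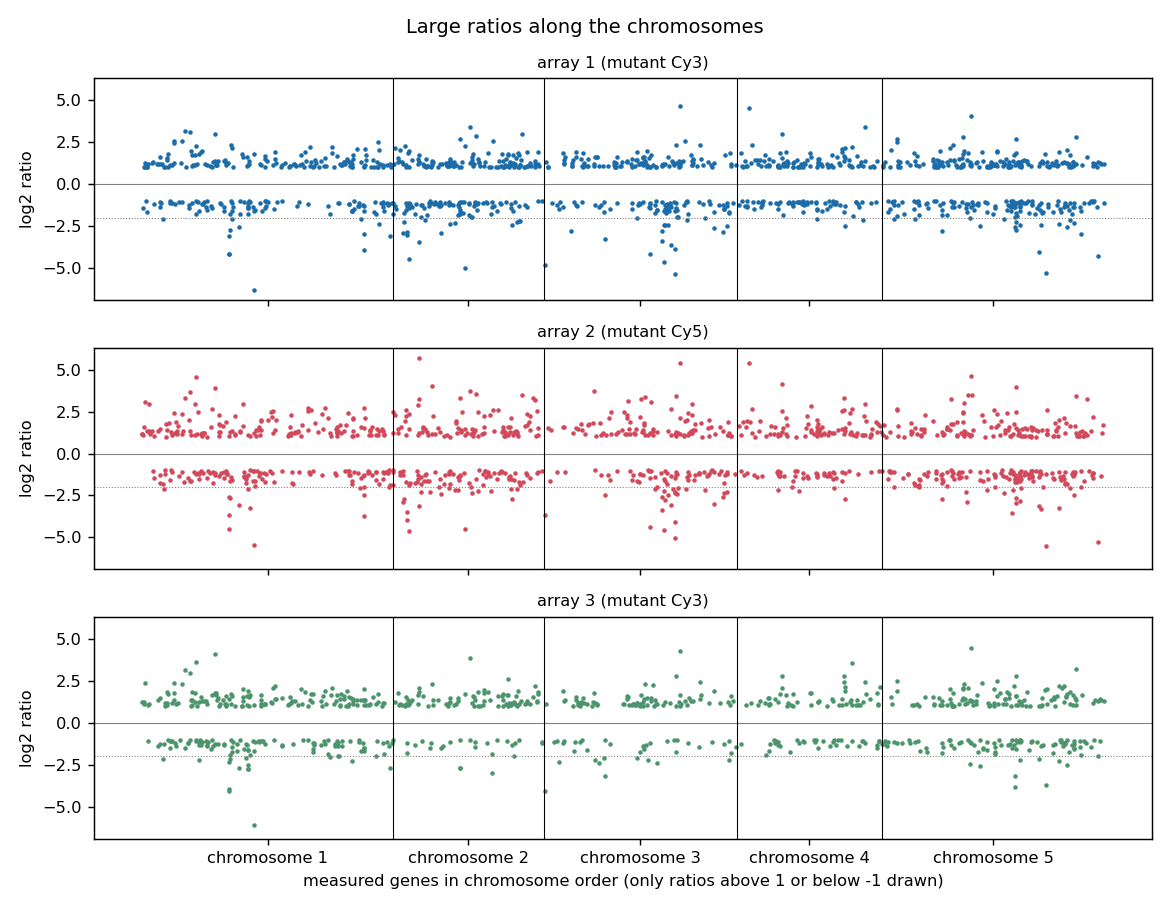
Log2 ratio (vertical axis) of genes above 1 or below -1 in chromosome order (horizontal axis), 1 panel per array, with a dotted line at -2. Deep falls near the start of chromosome 2 and in the middle of chromosome 3 appear on arrays 1 and 2, where the window from AT3G43291 to AT3G45490 holds 6 genes below -2 on both, and on array 3 that window holds 0.

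Of 105 called genes with 2 or more probes, 22 had probe means more than 1 apart, 16 of 57 among the lower and 6 of 48 among the higher genes; the difference between these shares was not tested. Without genes whose probes differ by that much, 262 genes passed, all among the 298, and without the 5 windows above 277 passed, 273 of them shared; both settings were chosen after the data were seen.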

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

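The tests in this part were chosen after the results they bear on were seen, except the count of sign patterns, which was planned.

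Probes without a gene name were left out of the gene-level comparison, and 52 of the 9346 passed the threshold when every probe was tested on its own, 25 higher and 27 lower in lsm1a lsm1b. They stand here because they lie outside the reported comparison; over all 43601 probes, named ones included, 273 passed. Probe A_84_P826646 had the highest mean ratio of these, 5.05 ± 0.75 (SD, n = 3 arrays; limma adjusted p = 0.0307), and A_84_P805080 the lowest, -3.63 ± 0.40 (adjusted p = 0.0262).

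The first pattern is that many strong falls were shared by arrays 1 and 2 alone: genes below -2 on arrays 1 and 2 but above -1 on array 3 numbered 26, and genes with the same split for arrays 1 and 3, or for 2 and 3, numbered 0 each. Mirrored rises, above 2 on 2 arrays and below 1 on the third, numbered 6 for arrays 1 and 2. They numbered 3 for arrays 1 and 3 and 3 for arrays 2 and 3. For the falls, dye bias would instead favour the 0 genes of arrays 1 and 3, which share a dye orientation. The counts therefore argue against dye bias as the source of these falls. A candidate explanation is that the mutant plants, or the Col-0 plants if the ratio runs the other way, carried chromosome segments of another accession: the 47 genes below -2 on arrays 1 and 2, whatever array 3 showed, formed 24 pairs, above the random range of 3 to 14. That closeness was seen before it was tested and is no independent support, and the positions of the 26 genes were not tested on their own. Since the 26 genes lay above -1 on array 3, the segments would have to differ between the replicate 3 plants and those of replicates 1 and 2. Whether the replicates differed in this way was not tested. Sequence differences under single probes may also have contributed to falls on arrays 1 and 2, whatever array 3 showed. Among genes with several probes and 1 probe below -2 on arrays 1 and 2, 35 of 52 had another probe above -1 on both (67.3%, 95% Wilson interval 53.8 to 78.5). The mirrored count for rises was 4 of 13 (30.8%, 12.7 to 57.6), with a one-sided Fisher exact p of 0.019. These 52 genes were not limited to the 26, which were not tested in this way on their own. Loss of the LSM1 subunit as a direct cause of single falls stays open and was not tested.

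The second pattern is that arrays 1 and 3 resembled each other more than array 2 over the bulk of genes, with Spearman's rho of 0.696 against 0.157 and 0.226. Dye bias may account for part of it. The 55 control features correlated between array 2 and array 1 at r = -0.351 (rho -0.381, permutation p = 0.0075, 0.011 after adjustment over 3 pairs). Between arrays 2 and 3 they correlated at r = -0.41 (rho -0.372, permutation p = 0.002, 0.006 after adjustment). Arrays 1 and 3 correlated at 0.261 (rho 0.314, permutation p = 0.056). The control features were told by their probe identifiers, and what they hold is not given in the sources used here. Control features are few and not independent replicates. Their largest absolute ratios were 0.39, 0.35 and 0.26 on arrays 1, 2 and 3, so they cover small ratios only. A difference of the replicate 2 plants themselves was not tested and stays open.

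The third pattern is the lower photosynthesis list. Dye bias as its whole cause would put array 2 at or above 0, but the list's median there was -0.38, and 15 of 17 members were below 0. The range of -0.14 to 0.16 holds 95% of 10000 random lists of 17 genes. Random lists hold unrelated genes, while the members of this list are correlated (estimated correlation 0.63), so that range is too narrow for it. Its members are not independent and array 2 is 1 array, so dye bias as the whole cause is not excluded. An effect of genotype or of the state of the plants stays open, and the size on array 2 was smaller than on the other arrays.

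The count of 298 genes was set against the other sign patterns of the 3 arrays. The real pattern was the 1 of 4 with as many genes and the highest other count was 0, but 4 patterns are too few for a share under 0.05.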

How the results depend on the processing

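The number of calls moved with the fit, and since each of the 298 genes had 1 sign on all 3 arrays, leaving out an array could not turn its direction. From 298 (154 higher, 144 lower) it went to 0 (0 and 0) with a dye term, with the opposite turning of array 2 and with the one-sample t-test, where 6389, 2402 and 2955 genes had an unadjusted p under 0.05. Of the 298, all did with the dye term and with the t-test, and 0 did with the opposite turning, which gives genes of 1 sign mixed signs. Since the 298 were chosen on the same arrays, these shares are no independent support. Leaving out 1 array gave 0 genes in each case (range 0 to 0), with lowest adjusted p from 0.074 to 0.25, although 2 simulated arrays gave calls. Robust moderation gave 181 (102 and 79, all among the 298), scale normalization 76 (38 and 38, 72 shared), single probes 193 genes (100 and 93, 149 shared) and array weights 9059 (4642 and 4417), with weights of 0.646, 0.278 and 5.57 that rest almost wholly on array 3. With single probes, 297 of the 298 genes kept their direction. An adjusted p under 0.01 left 6 (3 and 3), under 0.1 gave 1580 (855 and 725), and a 2-fold minimum left 190 (101 and 89). Centring (299, 297 shared), quantile normalization (296, 244 shared), medians over probes (300, 291 shared, chosen after the data were seen) and a 1.5-fold minimum (298) changed the total little. Quantile normalization did change which genes passed, with 166 higher and 130 lower. The dye coefficient itself was past the threshold for 0 genes by limma, with 4721 at an unadjusted p under 0.05, and 0 under centring and scale normalization.

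Of the 5 lists past the threshold, 0 held with an estimated correlation (adjusted p = 0.578 for each) or with fry in one direction (0.173 for photosynthesis, flavonoid, salicylic acid and heat shock, 0.322 for abscisic acid) or in either direction (0.0863 for flavonoid, 0.0896 for the others). With an estimated correlation, none of the 21 lists had an unadjusted camera p below 0.162. The senescence list went from an unadjusted camera p of 0.0373 to 0.162 although its estimated correlation was -0.018. The losses in this setting therefore cannot be laid to correlation between members alone. The dye term gave 7 lists, adding jasmonate (0.0425) and glucosinolate (0.000693). Leaving out arrays gave 4 to 10 lists, 4 without array 2 and 10 without array 1. Over these, adjusted p ranged from 0.000113 to 0.162 for heat shock, from 0.0184 to 0.301 for the other LSM genes, from 1.96e-06 to 0.806 for rapidly induced genes, from 0.0184 to 0.72 for oxidative stress, from 0.000505 to 0.962 for glucosinolate and from 0.00517 to 0.26 for senescence. Causes were not tested. Of the 22 named genes past the threshold, 7 missed it under scale normalization and 2 each under quantile normalization and single probes. No paired analysis was possible because each ratio already compares both genotypes within 1 array and there is 1 group of arrays. A filter on dim probes was not run, since no intensities were used, and a filter on missing values moved nothing, with 0 missing.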

Other observations

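The genes in this part were chosen after their values were seen. Single genes past the threshold of limma's test, which stand for no group, included CYP71A13, which acts in camalexin synthesis, at 1.94 ± 0.52 (SD, n = 3 arrays), DMR6, a salicylic acid hydroxylase gene, at 1.08 ± 0.23 and WRKY28 at 0.88. The metallothionein genes MT1A and MT2A stood at 1.59 and 1.48, and SGS3, a factor of RNA silencing, at 1.05. Lower in the mutant were PORA, a protochlorophyllide reductase gene, at -1.48, PETE1, a plastocyanin gene, at -0.96, EXPA1, an expansin gene, at -1.89 (probe means -2.50 and -1.27), and GA3OX1, a gibberellin synthesis gene, at -0.98. DAR4 stood at -2.44, its neighbour CSA1 at -1.60 and RRS1 at -0.96; each encodes a disease resistance protein of the NLR type, and other genes of that family were not tallied.

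AOP3, a glucosinolate side-chain gene, stood at 4.56, 5.41 and -0.12 on arrays 1, 2 and 3. RPS15AD had 1 probe at -6.76, -5.98 and 0.35 and another at -0.51, -0.19 and 0.32. Of the 4 probes of AT5G45490, 3 were below 0 on all arrays, at -4.44, -4.04 and -3.34, at -3.09, -3.10 and -2.23, and at -2.53, -3.02 and -2.29, and 1 was above 0, at 3.67, 3.54 and 3.74. The gene lies in the window from AT5G44270 to AT5G46200.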
